A study of Mus musculus with 20 samples.

How the data were processed

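Bulk RNA sequencing was measured in 20 mouse libraries from 8 groups. The 12 in vivo libraries came from GFP-positive, DAPI-negative cells sorted from lung tumours or neoplasias of 4 genotypes, with 3 libraries each. All 4 carried an allele of CreERT2, a Cre recombinase that tamoxifen activates. K carried the activated allele KrasFSF-G12D and 1 conditional Nkx2-1 allele (F/+). KN carried the same Kras allele and 2 conditional Nkx2-1 alleles (F/F). KNF1F2 had in addition F/F alleles of FoxA1 and FoxA2. N carried Nkx2-1F/F and no activated Kras allele. Mice received tamoxifen at 120 mg/kg in 4 injections over 5 days and then a 500 mg/kg tamoxifen diet for 7 days, and tissue was taken 8 weeks after tamoxifen, per the labels' protocols. The 8 other libraries came from 22E and KG1A, which are lines of tumour organoids (3-dimensional epithelial cultures) carrying the KNF1F2 alleles, with a p53FSF/+ allele in 22E only. Each line was treated for 48 hr with 4-hydroxytamoxifen (4OHT), the active tamoxifen metabolite used here to delete FoxA1 and FoxA2, or with its solvent ethanol (EtOH), and was collected 2 weeks later, with 2 libraries per line and treatment. Cultures grew in 50% conditioned medium from L-WRN cells, which secrete WNT3A, R-spondin 3 and noggin. In vivo libraries were made after ribosomal RNA depletion from at least 10 ng of RNA, and organoid libraries after poly(A) selection from at least 100 ng, all with a directional kit, per the labels' protocols. Levels were therefore not compared between in vivo and organoid libraries.

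The authors deposited 3 tables of raw counts, whole-number read counts per gene with no normalization, for the in vivo libraries, 22E and KG1A. Per the submitters' processing notes, cutadapt 3.5, STAR 2.7.6a, Subread and featureCounts 1.6.3 were used, and the builds mm39 and mm10 were named with no role or order given. Which build each table used, the strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here. Genes that overlap or share near-identical sequence, such as Muc3 and Muc3a, the Serpina1 family, the Gsdma and Gsdmc families and the Chil3, Chil4 and Chil6 genes, are therefore uncertain one by one. The tables held 24109, 18868 and 16697 genes. The lowest total of any gene was 6 counts in the in vivo and KG1A tables, so low totals had been removed there before deposit, while the 22E table kept 62 genes with no count. A gene symbol was missing for 178 in vivo genes and 24 KG1A genes, which stayed in the tests under their Ensembl identifiers and were not named. Identifiers were compared with GENCODE release M21 (GRCm38), which held 23710, 18839 and 16627 of them. It gave the positions printed and entered no test.

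Each deposited column was assigned to a library through its description label, and groups and replicate numbers came from the sample titles. The labels do not state whether replicates came from separate animals or cultures, so p-values measure the spread between these samples, part of which may be technical. The description labels also hold a request number for each library. K replicate 1, N replicate 1 and all KN and KNF1F2 libraries shared request 20040, K replicates 2 and 3 came from 20346, and N replicates 2 and 3 came from 20274. The 22E libraries shared 18994 and the KG1A libraries 19847. Before averaging, counts of each of the 16 pairs of replicates were compared by a chi-square statistic over genes. It ranged from 3.55 to 465 per degree of freedom, so no pair agreed within sampling noise and all libraries were kept as separate replicates.

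Total counts per library ran from 14066807 to 34260963 in vivo, from 20777088 to 30089059 in 22E and from 15337911 to 32584159 in KG1A. At those depths 1 count is worth well under 1 CPM (counts scaled to library size, after TMM, the trimmed mean of M values). For a gene with no count in a group, the fold change is given as a lower bound, computed against 3 counts over the summed libraries of that group. With 1 to 3 counts in a group, the ratio of pooled counts is given with its exact 95% interval. Floors and intervals cover counting error only.

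Differences between groups were tested in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM, glmQLFit and glmQLFTest), and a gene was called when its Benjamini-Hochberg adjusted p was under 0.05. The standard error (SE) of a log2 fold change was its size divided by the square root of the F statistic. The 12 in vivo libraries were fitted together, so that the 4 groups shared the estimate of spread, and KN was compared with K, KNF1F2 with KN, and KN with N. Each organoid line was fitted alone. The difference between the lines' responses to 4OHT was tested as the interaction of line and treatment over 8 libraries, among 16058 genes present in both tables. Means in the text are CPM with the SD over replicates. The tests, the samples in each, the alternatives and the rule for naming genes were fixed before the data were examined.

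Also fixed in advance were 19 gene lists with 266 genes in all: alveolar type 2, alveolar type 1, gastric surface mucous, gastric neck and chief, gut transcription factors, intestinal, squamous and squamocolumnar junction, liver secretory, tuft, airway club and ciliated, transitional alveolar, MAPK output, WNT targets, proliferation, dissociation stress, macrophage and neutrophil, lymphocyte, endothelial, and fibroblast and smooth muscle. The last 5 stand for handling of the tissue and for other cells the sort could hold. Each list with at least 3 tested members was tested with camera in limma 3.58.1, which compares the list's genes with all others, at a preset inter-gene correlation of 0.01 and with adjustment over the lists of that comparison. Camera was repeated with the correlation estimated from the residuals. With that estimate the calls of the intestinal list held in KN against K and in KNF1F2 against KN, and no other list's call held in any comparison. Counts of members past the threshold are given over all genes tested and adjusted over the list alone.

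The rule for named genes took, per comparison, 6 targeted or related genes (Nkx2-1, Foxa1, Foxa2, Foxa3, Kras and Trp53), and the 5 largest rises and 5 largest falls among called genes with a mean of at least 10 CPM in the higher group and no overlap between the libraries of the groups. Unnamed, predicted, mitochondrial, immunoglobulin and T-cell receptor genes were left out of these. It added up to 2 called members of each list with the largest change. Further list members named in the text (for example those that moved against the rest of their list), Clu, Rn18s-rs5, Ddx3y, and Meg3, Rian and Dlk1 outside KN against N were chosen after their values were seen.

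The alternatives were DESeq2 size factors or library totals in place of TMM, no count filter, a filter of at least 10 counts in every library of a group, the DESeq2 1.42.0 Wald test, a 2-fold minimum, the replicate number as a block, each library left out in turn, the 6 libraries of each pair of groups alone, the request number as a term, only the libraries of the shared request, per-line fold changes for the interaction, and other gene list tests (estimated correlation, fry, and lists without shared genes). Where leaving out a library, the request term or the shared request left 1 library of a group, that library was assumed to vary like the other groups. Removal of ribosomal RNA genes, log2 Xist CPM as a covariate, the omission of 2 in vivo libraries together, KG1A alone in the comparison with KNF1F2, and the repeats of the overlaps without each library were chosen after seeing the data.

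The tests were checked on independently simulated genes with the real means and library sizes, 100 changed 2-fold and 100 4-fold. The share recovered was 32% and 78% for KN against K among 17860 genes, 52% and 83% for KNF1F2 against KN, and 52% and 81% for KN against N. It was 67% and 95% for KG1A among 14152 genes, 0% and 0% for 22E among 15017 genes, and 0% and 6% for the interaction among 15094 genes. False calls made up 5.17% of calls for KN against K, 1.46% for KNF1F2 against KN, 1.48% for KN against N, 12.9% for KG1A and 14.3% (1 gene) for the interaction. The list of changed genes was called in every comparison and 0 of 18 random lists, which leaves the preset correlation unchecked.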

Results

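RNA was sequenced from mouse lung tumour cells carrying conditional alleles of the lung lineage factor Nkx2-1 and of the forkhead factors FoxA1 and FoxA2, with or without an activated Kras allele, and from 2 tumour organoid lines. The series asked which expression changes in sorted tumour cells depend on FoxA1 and FoxA2 and which on KRAS, and whether organoids need FoxA1 and FoxA2 to maintain a gastric programme. The 20 libraries held 3 of each in vivo genotype (K, KN, KNF1F2 and N) and 2 of each organoid line and treatment. Total counts were 14066807, 23639185 and 24279624 in K, 16472807, 14872474 and 15190732 in KN, 14180661, 16879907 and 19618169 in KNF1F2, and 15452984, 29204208 and 34260963 in N. They were 26014313 and 30089059 in 22E with EtOH, 20777088 and 22869999 in 22E with 4OHT, 15337911 and 25929298 in KG1A with EtOH, and 32584159 and 24065161 in KG1A with 4OHT. Values below are mean ± SD CPM over n = 3 libraries in vivo and n = 2 in organoids, and adjusted p-values of single genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

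The in vivo libraries separated by genotype. The correlation of log2 CPM across genes, which are not independent replicates, was 0.942 to 0.985 within groups and 0.798 to 0.936 between them, and the first 2 principal components held 36.3% and 31.1% of the variance. The most abundant transcript in K was Sftpc, the surfactant protein C of alveolar type 2 cells, with 4.55%, 3.60% and 4.24% of counts. In KN it was Clu, which encodes the secreted chaperone clusterin, with 4.28%, 4.16% and 3.38%. K replicate 1 and N replicate 1, which shared a library request with all KN and KNF1F2 libraries, detected 17114 and 19072 genes against 21333 to 22169 in the other in vivo libraries. K replicate 1 correlated at 0.942 and 0.944 with the other K libraries, which correlated at 0.985 with each other. In KG1A the correlations were 0.977 to 0.995 within and 0.882 to 0.903 between treatments. In 22E they were 0.925 to 0.942 within labelled treatments and 0.927 to 0.980 between them.

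The targeted genes were examined first. Nkx2-1 (ENSMUSG00000001496; GRCm38 chromosome 12, 56531958 to 56536908, minus strand) was at 421 ± 58.8 CPM in K, 95.6 ± 4.38 in KN, 121 ± 15.3 in KNF1F2 and 161 ± 10.5 in N. Foxa1 (ENSMUSG00000035451; chromosome 12, 57540628 to 57546916, minus strand) was at 114 ± 12.6 CPM in K, 336 ± 18.6 in KN, 41.4 ± 3.39 in KNF1F2 and 346 ± 30.1 in N. Foxa2 (ENSMUSG00000037025; chromosome 2, 148042877 to 148046969, minus strand) was at 120.3 ± 12.6, 35.7 ± 6.74, 7.01 ± 1.89 and 37.0 ± 13.1 CPM in the same order. The related Foxa3 (ENSMUSG00000040891; chromosome 7, 19013284 to 19023538, minus strand), which was not targeted, was at 6.79 ± 3.49 CPM in K, 77.2 ± 17.7 in KN, 0.628 ± 0.207 in KNF1F2 and 37.4 ± 2.58 in N. Kras was at 140.5 ± 8.27 CPM in K, 82.8 ± 13.6 in KN, 81.6 ± 7.83 in KNF1F2 and 51.2 ± 10.5 in N. In KG1A, 4OHT lowered Foxa1 from 161 ± 34.9 to 10.6 ± 0.342 CPM and Foxa2 from 49.6 ± 3.09 to 0.683 ± 0.00913. In 22E the targets did not follow the labels. Foxa1 was at 151 and 19.5 CPM in the EtOH libraries and at 137 and 14.0 in the 4OHT libraries, and Foxa2 at 18.6 and 0.540 against 18.2 and 0.428. Counts cover whole genes, and the exons that the conditional alleles remove are not given in the sources used here, so counts left after deletion can include exons outside the deleted part.

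**Figure D1:**
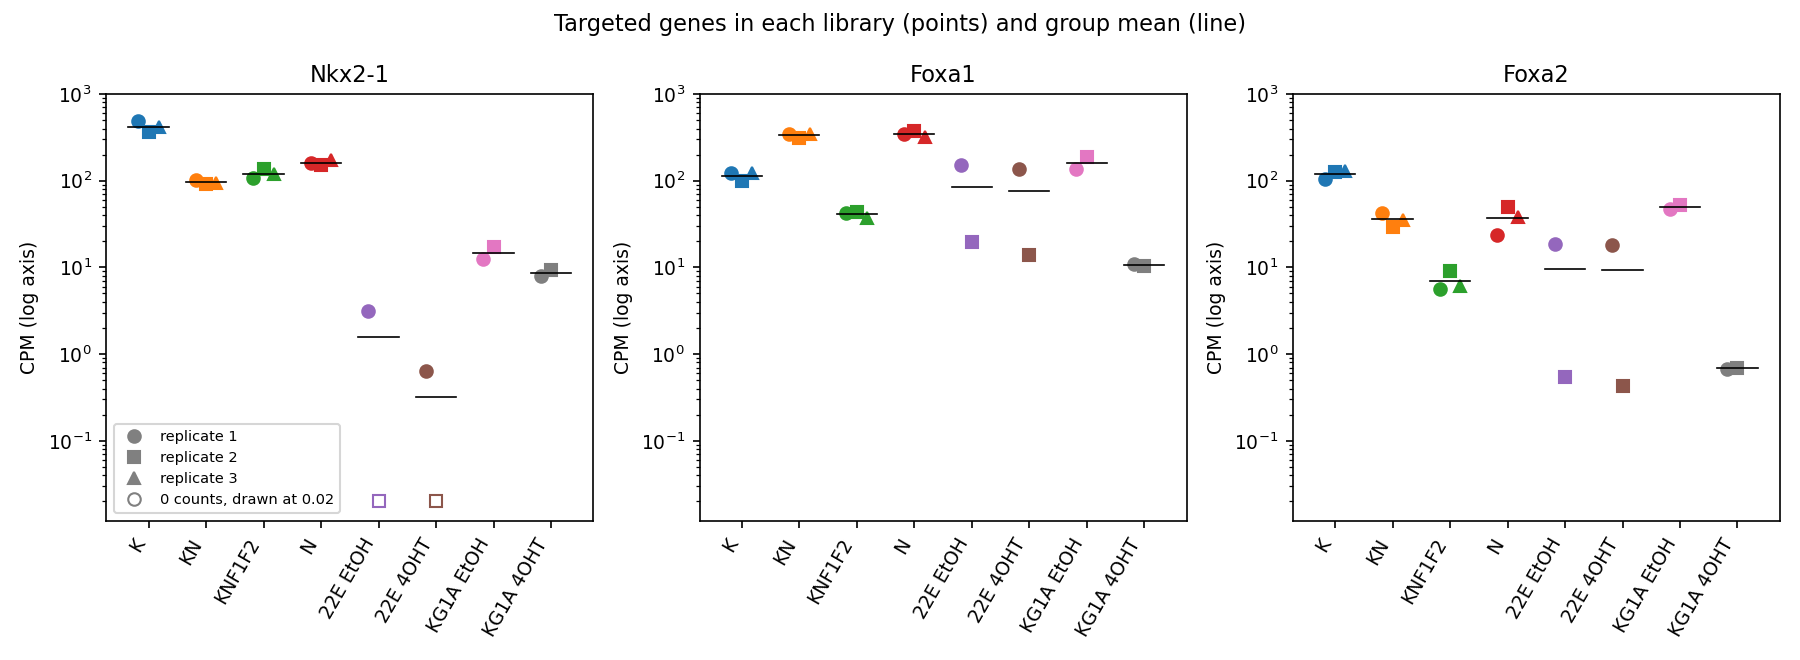
CPM (log axis) of Nkx2-1, Foxa1 and Foxa2 in each library (points, shaped by replicate number) by group, with the group mean as a line and libraries with 0 counts drawn as open points at the bottom. Foxa1 ran from 336 CPM in KN to 41.4 in KNF1F2 on average, whereas in 22E the libraries labelled EtOH lay at 151 and 19.5 CPM and those labelled 4OHT at 137 and 14.0.

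The comparison of KN with K asked what changed when both Nkx2-1 alleles were conditional instead of 1. Alveolar genes were lower in KN, and genes of the gastric surface, of tuft cells (chemosensory epithelial cells) and of the intestine were higher. All 16 alveolar type 2 genes fell, 14 of 15 gastric surface mucous genes rose, and 11 of 12 tuft genes rose. Nkx2-1 itself fell by 2.14 on the log2 scale (SE 0.13, edgeR adjusted p = 8.14e-08). Of 17860 genes tested, 7069 were called, 3640 higher and 3429 lower in KN (3514 and 3565 with DESeq2 size factors).

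The alveolar type 2 genes were among the most abundant transcripts that fell (16 of 16, also 16 adjusted over the list alone; camera adjusted p = 1.85e-10, and adjusted p = 0.129 with an estimated correlation). Sftpc fell from 43996 ± 4344 CPM in K to 1953 ± 400.2 in KN (log2 change -4.49, SE 0.65, edgeR adjusted p = 0.000125). Napsa, the aspartic protease that processes surfactant protein B, fell from 1277 ± 109.9 to 75.8 ± 4.65 CPM (log2 change -4.07, SE 0.43, edgeR adjusted p = 8.09e-06). Of 15 alveolar type 1 genes, 1 rose, 13 fell and 1 did not pass, with 1 and 14 adjusted over the list alone (camera adjusted p = 3.89e-08, and adjusted p = 0.0900 with an estimated correlation). Ager, the receptor for advanced glycation end products, fell from 1144 ± 168 to 61.3 ± 8.75 CPM, and the scaffold gene Akap5 from 178 ± 13.2 to 9.41 ± 2.85. The member that rose was Cldn18, a tight junction claudin of both lung and stomach, from 1404 ± 157 to 3210 ± 287 CPM (log2 change 1.19, edgeR adjusted p = 0.00937). With the request number as a term its change was 1.16 (edgeR adjusted p = 0.0629), and within the shared request 1.18 (edgeR adjusted p = 0.0826).

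Most gastric surface mucous and intestinal genes rose. Of 15 gastric surface mucous genes, 14 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 9.39e-08, and adjusted p = 0.0900 with an estimated correlation). Tff1, a mucosal trefoil peptide, rose from 34.9 ± 21.4 to 10548 ± 1368 CPM (log2 change 8.24, SE 0.97, edgeR adjusted p = 2.24e-05; 8.85 without K replicate 2). Gkn1, a peptide of gastric surface cells, rose from 7.51 ± 5.94 to 2566 ± 1446 CPM (log2 change 8.39, SE 0.80, edgeR adjusted p = 3.47e-06; 9.26 without K replicate 2). The member that fell was Pla2g1b, a secreted phospholipase, from 29.8 ± 5.76 to 3.5 ± 0.961 CPM. The 10 gastric neck and chief genes were divided, 4 up and 6 down, with the same counts adjusted over the list alone (camera adjusted p = 0.281), and their median and camera direction were negative while their mean was positive. Tff2, the trefoil peptide of neck cells, rose from 3.88 ± 1.70 to 1019 ± 576 CPM (log2 change 8.00, SE 0.56, edgeR adjusted p = 2.84e-07). Cblif, which encodes gastric intrinsic factor, was at least 20.8-fold lower in KN, where it had no count. The acidic chitinase gene Chia1 fell from 270 ± 36.9 to 8.89 ± 1.87 CPM. Of 13 gut transcription factors, 12 rose, 0 fell and 1 did not pass, with 13 up adjusted over the list alone (camera adjusted p = 2.66e-07, and adjusted p = 0.0900 with an estimated correlation). Pdx1, the pancreas and antral stomach factor, had 2 counts in K and was at 10.03 ± 3.57 CPM in KN, a ratio of 287 (counting interval 78.8 to 2373; log2 change 7.95, 10.64 without K replicate 2 and 7.35 without K replicate 3). Hnf4g rose to 17.5 ± 0.293 CPM (log2 change 7.12, 11.45 without K replicate 2 and 6.46 without K replicate 3). Of 10 intestinal genes, 7 rose and 3 did not pass, with 9 up adjusted over the list alone (camera adjusted p = 3.58e-05, and adjusted p = 0.0399 with an estimated correlation). Spink4, a protease inhibitor of goblet cells, was at 56.9 ± 13.6 CPM in KN and at least 1105-fold higher than in K, where it had no count (edgeR adjusted p = 4.06e-07). Tff3 rose to 778 ± 287 CPM (log2 change 9.33, 10.77 without K replicate 2). The intestinal mucin gene Muc3, uncertain against its paralog Muc3a, was at least 1309-fold higher (fitted log2 change 13.39, 14.01 without KN replicate 2). Of 12 tuft genes, 11 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 9.39e-08, and adjusted p = 0.0900 with an estimated correlation). Chat, the acetylcholine synthase, was at 4.29 ± 0.621 CPM in KN and at least 82.3-fold higher, and Rgs13 at least 416-fold higher at 21.8 ± 4.50 CPM, both with no count in K. The tuft member that fell was Ptgs1, the cyclooxygenase 1 gene, from 373 ± 43.4 to 58.4 ± 7.80 CPM.

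Other epithelial and signalling lists moved less evenly. Of 17 squamous genes, 7 rose, 0 fell and 10 did not pass, with 7 up adjusted over the list alone (camera adjusted p = 0.0292, and adjusted p = 0.465 with an estimated correlation). The keratin gene Krt4 rose from 0.425 ± 0.371 to 14.6 ± 2.76 CPM (log2 change 4.95, SE 0.49, edgeR adjusted p = 5.49e-06). Of 8 liver secretory genes, 2 rose, 2 fell and 4 did not pass, with the same calls adjusted over the list alone (camera adjusted p = 0.523). The carrier gene Ttr rose from 0.410 ± 0.391 to 160.0 ± 29.9 CPM (log2 change 8.42, SE 0.44, edgeR adjusted p = 3.40e-08; 9.14 without K replicate 2), while Alb, for albumin, fell from 18 ± 12.1 to 0.581 ± 0.266 (log2 change -4.95, SE 0.72, edgeR adjusted p = 0.000123). The 12 airway genes had 2 up, 4 down and 6 not passed, with 2 and 5 adjusted over the list alone (camera adjusted p = 0.512), among them Aldh1a1, a retinal dehydrogenase, which rose from 15.6 ± 1.19 to 192 ± 27.1 CPM. The 14 transitional alveolar genes had 5 up, 5 down and 4 not passed, with 6 and 5 adjusted over the list alone (camera adjusted p = 0.677), and their median and mean differed in sign. Krt8, a simple epithelial keratin, rose from 869 ± 222 to 3521 ± 89.2 CPM, and Slc4a11, an ion transporter, fell from 25.9 ± 7.23 to 3.75 ± 0.392. The 16 MAPK output genes had 4 up, 7 down and 5 not passed, with 4 and 8 adjusted over the list alone (camera adjusted p = 0.103). Etv5, an ETS factor downstream of FGF and MAPK, fell from 848 ± 98.0 to 35.6 ± 5.84 CPM (log2 change -4.57, SE 0.28, edgeR adjusted p = 9.44e-08), and the related Etv1 rose from 9.70 ± 3.51 to 42.1 ± 5.51 (log2 change 2.10, SE 0.43, edgeR adjusted p = 0.00163). The 11 WNT targets had 1 up, 5 down and 5 not passed, with 2 and 5 adjusted over the list alone (camera adjusted p = 0.0528, 0.0225 without KN replicate 2 and 0.0402 with the request as a term). Notum, a secreted WNT inhibitor, fell by 4.64 on the log2 scale and Sp5 fell by 4.14, while Lgr5, an R-spondin receptor, rose by 4.02 from 0.0757 ± 0.0691 to 1.49 ± 0.801 CPM. Of 16 proliferation genes, 3 fell and 13 did not pass, with 2 down adjusted over the list alone (camera adjusted p = 0.112, 0.0131 without K replicate 1). The mitotic checkpoint kinase gene Bub1 fell by 1.54 (SE 0.29, edgeR adjusted p = 0.0009).

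Markers of handling and of other cells changed in part along with these groups. Of 12 endothelial genes, 9 fell and 3 did not pass, with 9 down adjusted over the list alone (camera adjusted p = 0.000497, and adjusted p = 0.465 with an estimated correlation). Esam, an endothelial adhesion gene, fell from 103 ± 6.98 to 9.67 ± 2.65 CPM, and the VEGF receptor gene Kdr from 30.1 ± 3.26 to 4.12 ± 2.10. Of 14 macrophage and neutrophil genes, 2 rose, 1 fell and 11 did not pass, with the same calls adjusted over the list alone (camera adjusted p = 0.112, 0.0362 without KN replicate 1). The neutrophil gene Retnlg fell from 11.5 ± 3.89 to 0.865 ± 0.410 CPM. Of 12 lymphocyte genes, 1 rose, 1 fell and 10 did not pass, with 0 either way adjusted over the list alone (camera adjusted p = 0.769, 0.0229 without KN replicate 2), and their median and mean were positive while the camera direction was negative. Only KN replicate 2 was high, with a mean log2(CPM + 1) of 2.80 against 0.861 and 0.944 in KN replicates 1 and 3 and 1.29 to 1.58 in K. Of 10 fibroblast and smooth muscle genes, 1 fell and 9 did not pass, with 0 adjusted over the list alone (camera adjusted p = 0.112, 0.0202 with the request as a term and 0.00432 within the shared request). Of 12 dissociation stress genes, 5 rose and 7 did not pass, with 5 up adjusted over the list alone (camera adjusted p = 0.0532, 0.00966 without K replicate 1 and 0.0499 without KN replicate 3). Zfp36, an immediate early gene, rose from 358 ± 16.7 to 714 ± 108 CPM (edgeR adjusted p = 0.00278, and 0.0642 within the shared request).

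Among other large changes, Rerg, a small GTPase gene, had no count in KN and was at least 289.6-fold lower than in K, where it was at 19.3 ± 2.20 CPM (edgeR adjusted p = 6.91e-05). The gasdermin gene Gsdma2, uncertain against its paralogs, was at least 450.5-fold higher in KN (fitted log2 change 11.84, 11.20 without KN replicate 1). Gzme, a granzyme gene, had 1 count in KN (ratio 717, counting interval 128 to 28360.0; log2 change -9.04, -8.0 without K replicate 2 and -11.29 without KN replicate 2). Fbn2 fell by 8.06 and Tmem132d by 7.87 on the log2 scale (-9.35 and -8.59 without KN replicate 2). Xist, the transcript of the inactive X chromosome, was at 1.53, 1740 and 1896 CPM in K and 0.222 ± 0.0896 in KN. Its edgeR adjusted p was 0.0355, and 0.0541 to 0.104 without K replicate 2 or 3 or any KN replicate. Xist was high in K replicates 2 and 3 only and marks sex (below), so no effect of genotype is drawn from it. Foxa1 rose by 1.56 (SE 0.11, edgeR adjusted p = 3.63e-07) and Foxa3 by 3.49 (SE 0.31, edgeR adjusted p = 2.11e-06), while Foxa2 fell by 1.75 (SE 0.25, edgeR adjusted p = 0.000105) and Kras by 0.76 (SE 0.16, edgeR adjusted p = 0.00181). Trp53 rose by 0.38 (edgeR adjusted p = 0.0433), a call that ended without K replicate 1 (0.196), K replicate 2 (0.0545), KN replicate 1 (0.0886), KN replicate 2 (0.0842) or KN replicate 3 (0.0944). K replicates 2 and 3 came from a request of their own, so that a request term leaves K replicate 1 alone to stand for K. With that term 8859 genes were called, 5158 higher and 3701 lower, and 6074 of the 7069 were among them with no direction turned. Within the shared request, which held only K replicate 1 of that group, 9392 were called, 5477 higher and 3915 lower, and the median log2 change was 0.17.

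**Figure D2:**
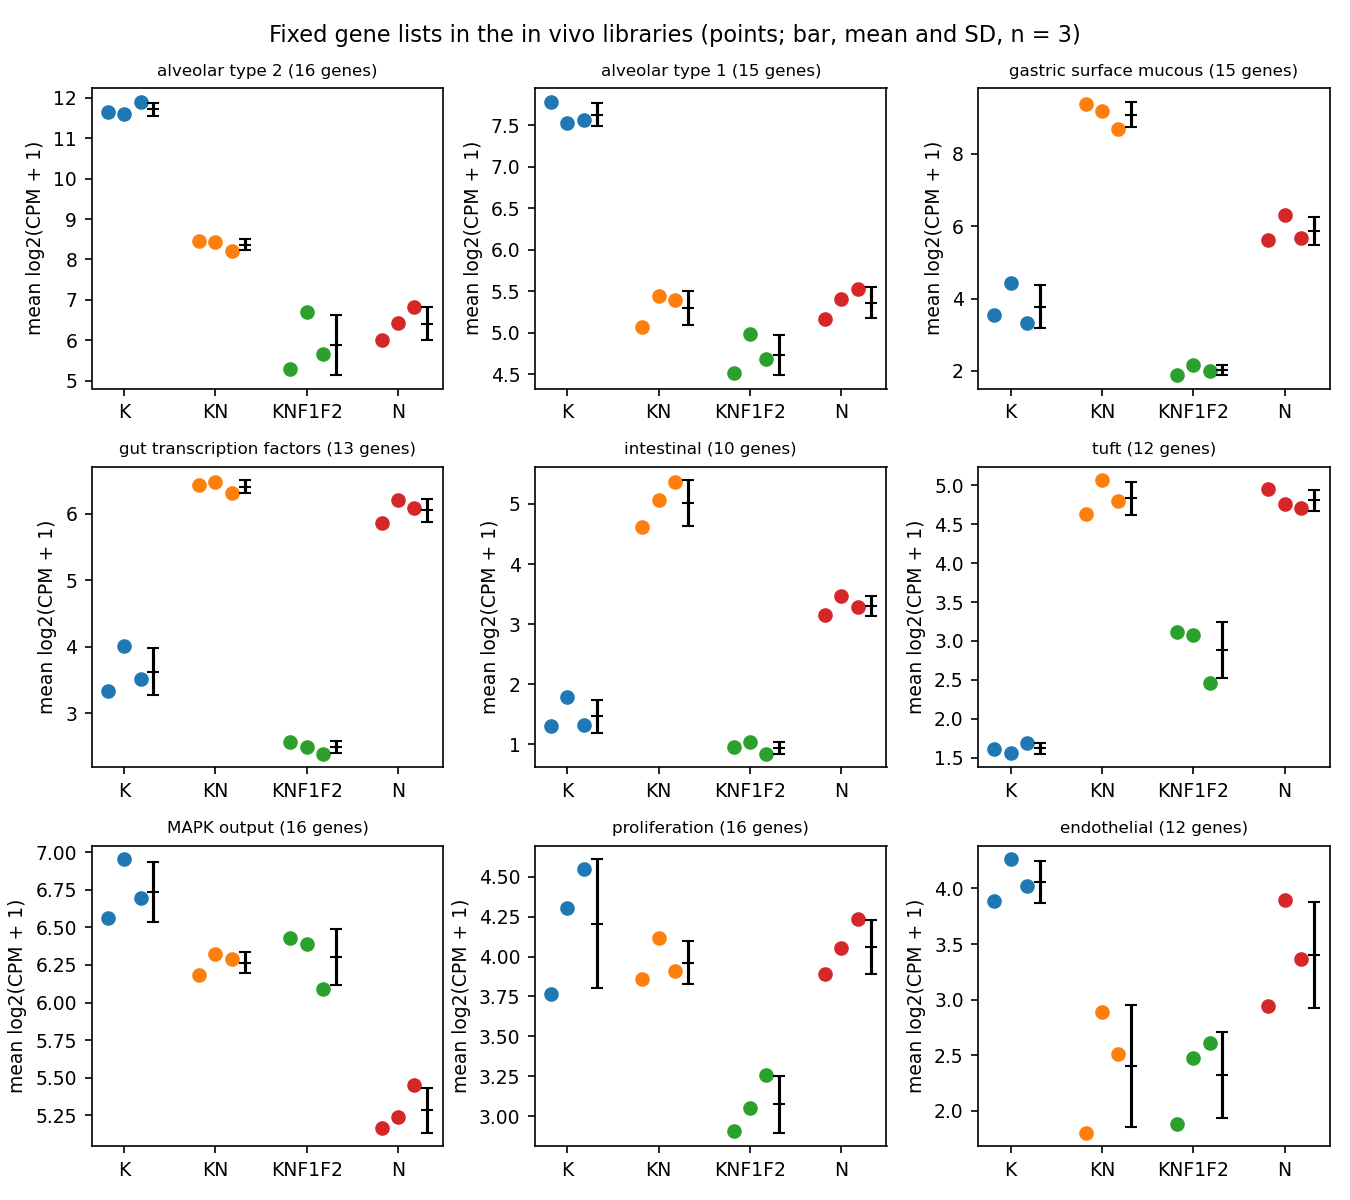
Mean log2(CPM + 1) over the genes of 9 of the fixed lists in each in vivo library (points), with the mean and SD of the 3 libraries of each group beside them; each panel has its own vertical axis, which does not start at 0. For the 15 gastric surface mucous genes, all KN libraries lie above all N libraries, these above all K libraries, and these above all KNF1F2 libraries.

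The comparison of KNF1F2 with KN asked which genes depended on FoxA1 and FoxA2 once Nkx2-1 had been targeted. The gastric surface, gut factor, intestinal and tuft genes were lower in KNF1F2. All 15 gastric surface mucous genes, 12 of 13 gut transcription factors, 9 of 10 intestinal genes and all 12 tuft genes fell. Most proliferation and alveolar type 2 genes fell too, 8 of 17 squamous genes rose, and airway (4 up, 3 down) and alveolar type 1 genes (5 up, 7 down) went both ways. Of 17860 genes, 6391 were called, 2909 higher and 3482 lower, and with library totals in place of TMM 3376 higher and 3057 lower. Foxa1 fell by 3.02 (SE 0.12, edgeR adjusted p = 7.00e-09), Foxa2 by 2.35 (SE 0.27, edgeR adjusted p = 1.89e-05) and Foxa3 by 6.97 (SE 0.40, edgeR adjusted p = 6.99e-08).

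For the gastric surface mucous list, 15 of 15 also fell adjusted over the list alone (camera adjusted p = 3.15e-12, and adjusted p = 0.0555 with an estimated correlation). Gkn1 fell from 2566 ± 1446 to 0.615 ± 0.768 CPM (log2 change -11.99, SE 0.96, edgeR adjusted p = 9.20e-07; -13.79 without KNF1F2 replicate 2). Muc5ac, the main gastric surface mucin, fell from 119 ± 81.4 to 0.360 ± 0.189 CPM (log2 change -8.31, SE 0.88, edgeR adjusted p = 1.03e-05). Gkn2 fell from 3645 ± 1908 to 1.03 ± 1.38 CPM (log2 change -11.79, -14.05 without KNF1F2 replicate 2 and -11.17 without KNF1F2 replicate 3). The 10 neck and chief genes had 3 up, 3 down and 4 not passed, with 3 each way adjusted over the list alone (camera adjusted p = 0.984), and their median and mean differed in sign. Tff2 fell by 8.70 (SE 0.58, edgeR adjusted p = 2.17e-07), and Pgc, the pepsinogen C gene, had 2 counts in KNF1F2 (ratio 211, counting interval 58.1 to 1752; log2 change -7.51, -6.88 without KNF1F2 replicate 3). Aqp5, a water channel, rose from 73.7 ± 13.5 to 1147 ± 66.9 CPM. For the gut transcription factors, 12 fell and 1 did not pass, with 12 down adjusted over the list alone (camera adjusted p = 1.00e-08, and adjusted p = 0.0561 with an estimated correlation). Hnf4a, a nuclear receptor of gut and liver epithelium, fell from 569.6 ± 35.1 to 2.80 ± 0.696 CPM, and Spdef, a factor of mucous and goblet cells, from 85.5 ± 16.9 to 0.289 ± 0.0597 (log2 change -8.16, SE 0.32, edgeR adjusted p = 6.32e-09). For the intestinal genes, 9 fell and 1 did not pass, with 1 up and 9 down adjusted over the list alone (camera adjusted p = 1.17e-05, and adjusted p = 0.0261 with an estimated correlation). Krt20, a keratin of differentiated gut epithelium, fell from 729 ± 221 to 0.807 ± 0.239 CPM (log2 change -9.85, SE 0.37, edgeR adjusted p = 5.33e-09), and Fabp2, the intestinal fatty acid binding protein gene, was at least 58.5-fold lower. For the tuft genes, 12 of 12 also fell adjusted over the list alone (camera adjusted p = 7.76e-07, and adjusted p = 0.139 with an estimated correlation), among them Avil from 197 ± 41.6 to 17.1 ± 4.36 CPM and Pou2f3, the tuft lineage factor, from 17.8 ± 1.75 to 6.99 ± 1.86. Of 8 liver genes, 3 fell and 5 did not pass, with 3 down adjusted over the list alone (camera adjusted p = 0.0287, and adjusted p = 0.614 with an estimated correlation), and Ttr fell from 160.0 ± 29.9 to 0.0789 ± 0.0334 CPM.

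The alveolar lists parted. Of 16 alveolar type 2 genes, 12 fell and 4 did not pass, with 12 down adjusted over the list alone (camera adjusted p = 1.34e-05, and adjusted p = 0.457 with an estimated correlation). Sftpb fell from 1745 ± 43.5 to 99.7 ± 103 CPM (log2 change -4.13, -5.44 without KNF1F2 replicate 2), and Cxcl15, the lung chemokine lungkine, by 4.15 (-5.42 without KNF1F2 replicate 2). Of 15 alveolar type 1 genes, 5 rose, 7 fell and 3 did not pass, with 5 and 7 adjusted over the list alone (camera adjusted p = 0.568). Cav1, which encodes the coat protein of caveolae, rose from 9.81 ± 2.00 to 373 ± 28.3 CPM (log2 change 5.25, SE 0.23, edgeR adjusted p = 9.74e-09), and Cldn18 fell from 3210 ± 287 to 15 ± 8.41 (log2 change -7.74, SE 0.42, edgeR adjusted p = 4.53e-08). The 14 transitional alveolar genes had 5 up, 4 down and 5 not passed, with 5 and 4 adjusted over the list alone (camera adjusted p = 0.770). The tight junction gene Cldn4 rose from 79.1 ± 14.3 to 554 ± 169 CPM, and the integrin gene Itgb6 fell from 166 ± 28.3 to 20.9 ± 6.16. Of 12 airway genes, 4 rose, 3 fell and 5 did not pass, with 4 and 3 adjusted over the list alone (camera adjusted p = 0.392). The dynein gene Dnah5 rose from 1.02 ± 0.319 to 18.2 ± 10.0 CPM and the club cell P450 gene Cyp2f2 from 137 ± 35.8 to 536 ± 232. Of 17 squamous genes, 8 rose and 9 did not pass, with 10 up and 1 down adjusted over the list alone (camera adjusted p = 0.0551, 0.0364 without KNF1F2 replicate 1 and 0.0162 without KNF1F2 replicate 2). Trp63, the basal cell factor p63, rose from 3.33 ± 0.838 to 32.9 ± 8.57 CPM (log2 change 3.31, SE 0.71, edgeR adjusted p = 0.00281). Krt14, a basal keratin, was at 5.27, 5.31 and 57.5 CPM in the KNF1F2 libraries against 0.18 ± 0.212 in KN (log2 change 6.93, edgeR adjusted p = 0.00318; 8.30 without KN replicate 3 and 4.83 without KNF1F2 replicate 3). Dsc3, a desmosomal cadherin, was at least 32.6-fold higher (fitted log2 change 8.37, 7.42 without KNF1F2 replicate 3).

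Of 16 proliferation genes, 14 fell and 2 did not pass, with 16 down adjusted over the list alone (camera adjusted p = 0.000143, and adjusted p = 0.457 with an estimated correlation), and the cycling marker Mki67 fell from 117 ± 20.5 to 43.3 ± 11.1 CPM (log2 change -1.43, SE 0.25, edgeR adjusted p = 0.000578). The 16 MAPK output genes had 6 up, 4 down and 6 not passed, with 7 and 6 adjusted over the list alone (camera adjusted p = 0.770). Spred1, an inhibitor of RAS signalling, rose from 123 ± 12.6 to 312 ± 35.4 CPM, and the ETS factor Etv4 fell from 24.6 ± 3.29 to 4.68 ± 2.08. The 11 WNT targets had 1 up, 3 down and 7 not passed, with the same calls adjusted over the list alone (camera adjusted p = 0.596), and Notum rose from 0.158 ± 0.0424 to 7.96 ± 1.39 CPM. Among markers of other cells, 1 of 12 endothelial genes rose and 11 did not pass, with 1 up adjusted over the list alone (camera adjusted p = 0.984). That gene was Esam, from 9.67 ± 2.65 to 37.7 ± 7.78 CPM. Of 12 lymphocyte genes 1 fell, as adjusted over the list alone (camera adjusted p = 0.984), namely Cd79b of B cells by 2.32 (-1.70 without KN replicate 2). Of 14 macrophage and neutrophil genes 1 fell, as adjusted over the list alone (camera adjusted p = 0.984), namely Marco. Its log2 change was -5.43, and -11.01 without KNF1F2 replicate 3 (edgeR adjusted p = 0.0122, and 0.0563 without KN replicate 3). The list's mean log2(CPM + 1) was 2.34, 2.02 and 3.64 in KNF1F2 replicates 1 to 3. Of 10 fibroblast genes, 0 were called by edgeR over all genes or adjusted over the list alone (camera adjusted p = 0.984), 0 had an unadjusted p under 0.05, and DESeq2 called 0. Of 12 dissociation stress genes, 1 rose, 2 fell and 9 did not pass, with the same calls adjusted over the list alone (camera adjusted p = 0.838), and Btg2 fell by 0.60 (SE 0.15, edgeR adjusted p = 0.00749). The stress, macrophage and fibroblast lists had medians, means or camera directions that differed in sign.

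The largest rises were of Chil6, a chitinase-like gene uncertain against its paralogs, from 0.0928 ± 0.0804 to 311 ± 63.3 CPM (log2 change 11.66, SE 0.45, edgeR adjusted p = 6.32e-09; 11.07 without KN replicate 1), and of genes with no count in KN. Btn1a1, a butyrophilin, was at least 400.2-fold higher, Chst9, a sulfotransferase, at least 174-fold, and Kcnc2, a potassium channel, at least 162-fold. Gsdmc2, uncertain against its paralogs, was at least 384-fold higher (fitted log2 change 11.98, 11.32 without KNF1F2 replicate 3). Fstl4 was at least 711-fold lower, the lipase gene Pnliprp2 at least 710.4-fold and the phospholipase gene Pla2g10 at least 553-fold, with no count in KNF1F2. Kras did not differ by the test (log2 change -0.02, SE 0.16, edgeR adjusted p = 0.940). Nkx2-1 was higher by 0.34 (SE 0.12, edgeR adjusted p = 0.0481), and was not called without KN replicate 1 (0.0718), KN replicate 2 (0.139), KN replicate 3 (0.113), KNF1F2 replicate 2 (0.213) or KNF1F2 replicate 3 (0.0990). All 6 libraries shared a request.

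Many genes went up with Nkx2-1 targeting and down with FoxA1 and FoxA2 targeting. Of the 3640 genes higher in KN than in K, 1903 (52.3%) were lower in KNF1F2 than in KN, where 709.7 would overlap if the lists were independent. The KN libraries enter both comparisons. In 20 simulations of unchanged groups edgeR called at most 2 genes per comparison, so their overlap of 0 measures no excess. The covariance of the log2 changes (-1.36 against -0.126 in the simulations) measures none either, since any real KN-specific expression lowers it. Across genes, which are not independent replicates, r was -0.434 against -0.511 in the simulations. A shared group sets the simulated r whatever the size of the noise, so r shows neither an excess nor the lack of one. A further 1285 genes were lower in KN than in K and higher in KNF1F2 than in KN, against 559 for independent lists. With 3 KN libraries the shared group could not be split, so its part in these overlaps is open.

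The comparison of KN with N asked which genes depended on the activated Kras allele among Nkx2-1-targeted cells. Most MAPK output (13 of 16), alveolar type 2 and gastric surface genes were higher in KN. Lower were 6 of 11 WNT targets and 6 of 8 liver secretory genes. No list call held with an estimated correlation. The gut transcription factors and tuft genes mostly did not pass the test. Of 17860 genes, 4853 were called, 2492 higher and 2361 lower.

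The MAPK output list rose with 13 of 16 genes, 0 down and 3 not passed, and 14 up adjusted over the list alone (camera adjusted p = 4.17e-07, and adjusted p = 0.132 with an estimated correlation). Dusp6, a phosphatase induced by ERK, rose from 55.3 ± 2.53 to 138 ± 11.9 CPM (log2 change 1.32, SE 0.18, edgeR adjusted p = 0.000214). Spry4, a feedback inhibitor of RAS signalling, rose from 5.55 ± 2.01 to 14.6 ± 1.54 CPM, and Etv1 from 10.4 ± 8.22 to 42.1 ± 5.51 (log2 change 2.06, 2.92 without N replicate 1). The WNT list had 0 up, 6 down and 5 not passed, with 6 down adjusted over the list alone (camera adjusted p = 8.99e-05, and adjusted p = 0.132 with an estimated correlation). Lgr5 fell from 20.6 ± 4.11 to 1.49 ± 0.801 CPM (log2 change -3.79, SE 0.46, edgeR adjusted p = 0.0001), and the feedback gene Axin2 from 22.0 ± 7.90 to 3.95 ± 1.06. Of 14 transitional alveolar genes, 8 rose, 2 fell and 4 did not pass, with 11 and 2 adjusted over the list alone (camera adjusted p = 0.0109, and adjusted p = 0.541 with an estimated correlation). The EGFR ligand gene Areg rose from 12.7 ± 4.36 to 80.7 ± 2.07 CPM. The members that fell were Hmga2, a chromatin protein gene, from 12.8 ± 1.76 to 0.676 ± 0.0706 and Itgb6 from 382 ± 21.3 to 166 ± 28.3. Of 16 proliferation genes, 2 fell and 14 did not pass, with 2 down adjusted over the list alone (camera adjusted p = 0.424), among them the replication gene Mcm2 by 0.85 (SE 0.14, edgeR adjusted p = 0.000642).

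Of 16 alveolar type 2 genes, 13 rose and 3 did not pass, with 14 up adjusted over the list alone (camera adjusted p = 2.90e-07, and adjusted p = 0.231 with an estimated correlation). Sftpb rose from 179 ± 84.1 to 1745 ± 43.5 CPM (log2 change 3.28, SE 0.61, edgeR adjusted p = 0.00182) and the chitinase-like gene Chil1 from 80.3 ± 16.3 to 1088 ± 277. Of 15 alveolar type 1 genes, 3 rose, 4 fell and 8 did not pass, with 3 and 5 adjusted over the list alone (camera adjusted p = 0.424). Cldn18 rose from 612 ± 187 to 3210 ± 287 CPM, and podoplanin (Pdpn) fell from 34.1 ± 8.40 to 14.5 ± 3.40. Of 15 gastric surface mucous genes, 10 rose, 1 fell and 4 did not pass, with 13 and 1 adjusted over the list alone (camera adjusted p = 3.03e-05, and adjusted p = 0.189 with an estimated correlation). Gkn1 rose from 0.140 ± 0.143 CPM (log2 change 13.91, SE 1.05, edgeR adjusted p = 4.40e-06; 14.73 without N replicate 2), Gkn2 by 10.91 (12.41 without N replicate 2), and Tff1 from 168 ± 167 CPM by 5.97 (7.20 without N replicate 2). The member that fell was the phospholipase gene Pla2g1b, from 79.5 ± 26.8 to 3.5 ± 0.961 CPM. The 10 neck and chief genes had 1 up, 6 down and 3 not passed, with 2 and 6 adjusted over the list alone (camera adjusted p = 0.0197, and adjusted p = 0.132 with an estimated correlation). Their camera call also ended with library totals (0.0844), with no count filter (0.111), without genes shared between lists (0.0545) and in the 6 libraries alone (0.150). Pgc fell from 743 ± 447 to 8.22 ± 0.541 CPM (log2 change -6.50, SE 0.43, edgeR adjusted p = 1.71e-06; -5.89 without N replicate 3), and Cblif was at least 31.4-fold lower (fitted log2 change -8.27, -7.01 without N replicate 3). Of 13 gut transcription factors, 3 rose, 2 fell and 8 did not pass, with 3 and 2 adjusted over the list alone (camera adjusted p = 0.544). Pdx1, with no count in N, was at least 286-fold higher in KN, and Hnf1b fell from 201 ± 61.5 to 94.7 ± 12.3 CPM. Of 10 intestinal genes, 5 rose, 1 fell and 4 did not pass, with 6 and 1 adjusted over the list alone (camera adjusted p = 0.0183, adjusted p = 0.132 with an estimated correlation, 0.0959 with the request as a term and 0.0545 within the shared request). Krt20 rose from 18.6 ± 3.49 to 729 ± 221 CPM and Tff3 from 13.9 ± 16.5 to 778 ± 287 (log2 change 5.78, 7.48 without N replicate 2), while Spink4 fell from 158 ± 78.8 to 56.9 ± 13.6. Of 12 tuft genes, 1 rose and 11 did not pass, as adjusted over the list alone (camera adjusted p = 0.989), namely Avil from 93.5 ± 6.46 to 197 ± 41.6 CPM.

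Of 8 liver genes, 6 fell and 2 did not pass, with 6 down adjusted over the list alone (camera adjusted p = 0.000486, and adjusted p = 0.231 with an estimated correlation). Alb fell from 113 ± 58.1 to 0.581 ± 0.266 CPM (log2 change -7.57, SE 0.73, edgeR adjusted p = 2.14e-05), and the trypsin inhibitor gene Serpina1a, uncertain against its paralogs, had 1 count in KN (ratio 682, counting interval 122 to 26952; log2 change -9.20, -11.43 without KN replicate 1). The carboxylesterase gene Ces1c fell by 8.30 (SE 0.77, edgeR adjusted p = 4.59e-05) and the growth factor gene Gdf10 fell by 7.69 (SE 0.63, edgeR adjusted p = 6.94e-06). Of 12 airway genes, 3 rose, 4 fell and 5 did not pass, with 3 and 7 adjusted over the list alone (camera adjusted p = 0.164). The ciliary genes Dnah5 and Ccdc39 and the ciliated cell factor Foxj1 fell, with log2 changes of -3.50, -4.35 and -1.76, and Aldh1a1 rose by 3.42. Of 17 squamous genes, 2 rose, 3 fell and 12 did not pass, with the same calls adjusted over the list alone (camera adjusted p = 0.976). Ivl, a cornified envelope gene, rose by 6.06 (9.71 without N replicate 3) and Trp63 by 3.96 (6.08 without N replicate 1 and 3.21 without N replicate 3). Among markers of other cells, 5 of 12 endothelial genes fell and 7 did not pass, with 5 down adjusted over the list alone (camera adjusted p = 0.00387, adjusted p = 0.541 with an estimated correlation, 0.355 with the request as a term, 0.477 within the shared request and 0.0532 by fry). Kdr fell by 1.95 (edgeR adjusted p = 0.00384), and with the request as a term its change was -1.48 (edgeR adjusted p = 0.0665). Of the 14 macrophage and neutrophil genes (camera adjusted p = 0.989), the 12 lymphocyte genes (0.424, and 0.000317 without KN replicate 2) and the 10 fibroblast genes (0.989), edgeR called 0, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 they held 6, 0 and 3 genes, and DESeq2 called 5, 0 and 0. Of 12 dissociation stress genes, 3 rose and 9 did not pass, with 3 up and 2 down adjusted over the list alone (camera adjusted p = 0.976), and the heat shock gene Hspa1b rose from 29.7 ± 1.44 to 122 ± 20.9 CPM. The tuft, lymphocyte and fibroblast lists had medians, means or camera directions that differed in sign.

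Nkx2-1 was lower in KN than in N (log2 change -0.75, SE 0.12, edgeR adjusted p = 0.000758), and Trp53 fell by 0.70 (SE 0.14, edgeR adjusted p = 0.00234). Kras was 0.69 higher (edgeR adjusted p = 0.00608), and 0.47 higher both with the request as a term (edgeR adjusted p = 0.139) and within the shared request (0.109). Foxa1 (log2 change -0.04, SE 0.11, edgeR adjusted p = 0.821) and Foxa2 (-0.06, SE 0.24, edgeR adjusted p = 0.900) did not differ by the test. Foxa3 was higher by 1.05 (SE 0.28, edgeR adjusted p = 0.0149), and was not called without N replicate 3 (0.0523) or KN replicate 1 (0.0708). Xist was at 1619 ± 1406 CPM in N, also split by sex. Its edgeR adjusted p was 0.0437, and 0.0649 to 0.131 without N replicate 1 or 3 or any KN replicate. N replicates 2 and 3 came from a request of their own, so that a request term leaves N replicate 1 alone to stand for N. With that term 4824 genes were called, 3258 of them among the 4853, and within the shared request, which held only N replicate 1 of that group, 5000 were called, 3179 of them among the 4853. With library totals in place of TMM, 5271 genes were called, 1497 higher and 3774 lower (28.4% higher against 51.4% with TMM), and the median log2 change was -0.20. Of the genes higher in KN than in K, 1255 (34.5%) were also higher in KN than in N, against 508 for independent lists. The covariance of the log2 changes (0.557 against 0.128 in simulations) measures no excess, since any real KN-specific expression raises it. Across genes r was 0.263 against 0.526 in the simulations. The part of the shared KN libraries in this overlap is open.

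The organoid comparisons asked whether established gastric expression was lost when FoxA1 and FoxA2 were deleted in culture. In KG1A, 4OHT lowered all 14 gastric surface mucous genes and all 7 intestinal genes tested, and raised all 3 fibroblast genes tested. Of 14152 genes, 4172 were called, 2288 higher and 1884 lower. Without EtOH replicate 1 or 2 the count was 8515 or 9159, and without 4OHT replicate 1 or 2 it was 1784 or 1931. With library totals in place of TMM it was 2898, 2066 higher and 832 lower (71.3% higher against 54.8%), and the median log2 change was 0.21. Ribosomal RNA gene Rn18s-rs5 took 20.4% of counts in EtOH replicate 1, and without ribosomal RNA genes 4170 genes were called.

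Foxa1 fell by 3.92 (SE 0.19, edgeR adjusted p = 0.000257), Foxa2 by 6.18 (SE 0.16, edgeR adjusted p = 9.14e-05) and Foxa3 fell by 2.83 (SE 0.24, edgeR adjusted p = 0.00128). Nkx2-1 fell from 14.8 ± 3.28 to 8.69 ± 1.04 CPM (edgeR adjusted p = 0.0415, and 0.235 with library totals). With its alleles also conditional and no line without FoxA alleles, a part of Nkx2-1 or of 4OHT itself stays open. Kras had a log2 change of -0.23 (edgeR adjusted p = 0.336), and Trp53 of 0.04 (edgeR adjusted p = 0.850). For the gastric surface mucous genes, 14 of 14 fell, also adjusted over the list alone (camera adjusted p = 9.52e-12, and adjusted p = 0.383 with an estimated correlation). Tff1 fell from 1243 ± 437 to 0.0857 ± 0.0414 CPM (log2 change -13.81, SE 0.50, edgeR adjusted p = 0.000165) and Gkn1 from 268 ± 22.4 to 0.170 CPM (log2 change -10.52, SE 0.24, edgeR adjusted p = 9.14e-05). Gkn2 was at least 6036-fold lower (fitted log2 change -15.61, -16.43 without EtOH replicate 1 and -14.52 without EtOH replicate 2). Of 7 neck and chief genes, 2 rose, 4 fell and 1 did not pass, with 3 and 4 adjusted over the list alone (camera adjusted p = 0.267, 0.0437 without 4OHT replicate 2). Pgc, with no count after 4OHT, was at least 2790.4-fold lower, and Dmbt1, a secreted mucosal scavenger receptor, rose from 382 ± 73.6 to 2030.1 ± 293 CPM. Of 13 gut transcription factors, 8 fell and 5 did not pass, with 10 down adjusted over the list alone (camera adjusted p = 7.07e-05, and adjusted p = 0.383 with an estimated correlation). Hnf4a fell from 313 ± 68.9 to 14.7 ± 0.253 CPM and Spdef from 46.5 ± 6.40 to 0.251 ± 0.0839. For the intestinal genes, 7 of 7 fell, also adjusted over the list alone (camera adjusted p = 0.000290, and adjusted p = 0.383 with an estimated correlation). Of 5 liver genes, 4 fell and 1 did not pass, with 4 down adjusted over the list alone (camera adjusted p = 0.00638, and adjusted p = 0.383 with an estimated correlation), and Ttr was at least 1473-fold lower. The endoplasmic reticulum stress sensor gene Ern2, of mucous cells, was at least 1502-fold lower. Of 7 tuft genes, 2 rose and 5 fell, with the same calls adjusted over the list alone (camera adjusted p = 0.0650, 0.0418 without 4OHT replicate 1 and 0.0296 without 4OHT replicate 2). It was 0.00396 with library totals and 0.00566 with no count filter. Pou2f3 fell from 2.12 ± 0.118 to 0.0857 ± 0.0414 CPM, whereas Dclk1, a kinase gene used as a tuft marker, rose from 2.56 ± 0.0727 to 93.6 ± 9.51 and Ptgs1 from 25.3 ± 4.67 to 69.8 ± 2.55.

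Cyp2f2 had no count with EtOH and was at least 1691-fold higher with 4OHT, at 129.8 ± 18.9 CPM (edgeR adjusted p = 0.000199). The collagen gene Col8a1 was at least 490.1-fold higher, the WNT modulator gene Sfrp2 at least 358-fold, the bradykinin receptor gene Bdkrb2 at least 197.5-fold and the adhesion receptor gene Adgra1 at least 167-fold. Of 7 airway genes, 2 rose, 1 fell and 4 did not pass, with 3 and 1 adjusted over the list alone (camera adjusted p = 0.156). Of 12 alveolar type 1 genes, 6 rose, 3 fell and 3 did not pass, with 7 and 3 adjusted over the list alone (camera adjusted p = 0.131). Cav1 rose from 16.5 ± 5.41 to 235 ± 3.21 CPM (log2 change 3.81, SE 0.24, edgeR adjusted p = 0.000490) and the basement membrane gene Col4a3 from 0.0954 to 7.29 ± 0.0974, and Cldn18 fell from 551 ± 4.90 to 98.1 ± 0.331. Of 9 alveolar type 2 genes, 3 rose, 1 fell and 5 did not pass, with 3 and 1 adjusted over the list alone (camera adjusted p = 0.440). Slc34a2, a phosphate transporter, rose by 6.89 (8.28 without EtOH replicate 2), and Cxcl15 was at least 93.0-fold lower. Of 7 squamous genes, 3 rose, 1 fell and 3 did not pass, with 5 and 1 adjusted over the list alone (camera adjusted p = 0.156), and the member that fell was the envelope gene Sprr1a by 1.92. Of 14 transitional alveolar genes, 2 rose, 4 fell and 8 did not pass, with 2 and 4 adjusted over the list alone (camera adjusted p = 0.156), among them Hmga2 up by 1.63 and Areg down from 89.7 ± 11.5 to 10.2 ± 1.07 CPM. Of 16 MAPK output genes, 6 rose, 4 fell and 6 did not pass, with 7 and 4 adjusted over the list alone (camera adjusted p = 0.440), and Phlda1 fell from 849 ± 3.29 to 242 ± 4.60 CPM. Of 9 WNT targets, 5 rose, 1 fell and 3 did not pass, with 5 and 2 adjusted over the list alone (camera adjusted p = 0.267). Lgr5 rose from 27.3 ± 0.949 to 68.1 ± 5.56 CPM, and Sp5 fell from 34.5 ± 1.53 to 2.61 ± 0.012. Of 16 proliferation genes, 8 fell and 8 did not pass, with 10 down adjusted over the list alone (camera adjusted p = 0.000713, and adjusted p = 0.383 with an estimated correlation), and Birc5, the survivin gene, fell by 1.36 (SE 0.27, edgeR adjusted p = 0.0164). Of 12 dissociation stress genes, 1 rose, 5 fell and 6 did not pass, with 2 and 5 adjusted over the list alone (camera adjusted p = 0.440). Jun rose by 0.98 and Atf3 fell by 1.70. The 3 fibroblast genes tested rose, also adjusted over the list alone (camera adjusted p = 0.00934, adjusted p = 0.383 with an estimated correlation, and 0.0599 without EtOH replicate 2), including the fibronectin gene Fn1 from 273 ± 83.5 to 1271 ± 47.2 CPM and Col1a1 from 0.522 ± 0.0698 to 5.02 ± 0.597. Of 5 endothelial genes, 3 rose and 2 did not pass, with 3 up and 1 down adjusted over the list alone (camera adjusted p = 0.0721, 0.0437 without 4OHT replicate 2), and Kdr was at least 15.5-fold higher. Of 3 macrophage genes, 1 rose, with 1 up and 1 down adjusted over the list alone (camera adjusted p = 0.966), namely Csf1r by 1.53 (edgeR adjusted p = 0.0310; 0.288 without 4OHT replicate 1 and 0.285 without 4OHT replicate 2). The lymphocyte list had 2 tested members and no camera test; edgeR called 0, 0 had an unadjusted p under 0.05, and DESeq2 called 0. The alveolar type 2 and macrophage lists had medians, means or camera directions that differed in sign.

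In 22E, edgeR called 0 of 15017 genes between the libraries labelled 4OHT and EtOH, with 416 at an unadjusted p under 0.05, and DESeq2 called 10. Foxa1 had a log2 change of -0.18 (SE 1.41) and Foxa2 of -0.04 (SE 2.12), both with an edgeR adjusted p of 1.00. The libraries resembled each other by replicate number and not by labelled treatment. The library labelled EtOH replicate 1 correlated at 0.977 with that labelled 4OHT replicate 1, and those numbered 2 at 0.980, against 0.942 and 0.925 within the labelled treatments. Tff1, Hnf4a and Cyp2f2 were divided the same way. Tff1 was at 297 and 2.23 CPM in the libraries labelled EtOH and at 147 and 0 in those labelled 4OHT, and Hnf4a at 180 and 8.40 against 155 and 7.66. Cyp2f2 was at 0.691 and 84.6 against 0.972 and 21.5 CPM. No direction is drawn from these labels. Over all genes edgeR called 0 members of each list, 0 to 2 per list had an unadjusted p under 0.05, and DESeq2 called 0. Adjusted over the list alone, 1 fibroblast gene was called and 0 of the other lists. The proliferation list of 16 genes was past the threshold between the labels (camera adjusted p = 0.000301, adjusted p = 0.823 with an estimated correlation, 0.965 by fry, 0.0860 without EtOH replicate 1 and 0.427 without 4OHT replicate 1). Camera adjusted p was 0.0682 for the airway list (0.0240 without 4OHT replicate 1) and also 0.0682 for MAPK output (0.0345 without EtOH replicate 2 and 0.0240 without 4OHT replicate 1). It was 0.168 for the alveolar type 2 list, 0.710 for alveolar type 1, 0.895 for WNT, 0.421 for squamous and 0.556 for tuft genes. The gastric surface list had 0.556 (0.0124 without EtOH replicate 2) and the intestinal list 0.484 (0.0240 without 4OHT replicate 1). The neck and chief, gut factor, liver, transitional, stress, macrophage and endothelial lists had 0.484. The lymphocyte and fibroblast lists had 2 tested members each and no camera test.

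The interaction of line and treatment, which compared the libraries labelled by treatment in 22E with those in KG1A, was called for 36 of 15094 genes, 8 with a higher and 28 with a lower log2 change in 22E than in KG1A, and 2322 had an unadjusted p under 0.05. Without single libraries the count ran from 0 to 242. It was 242 without the library labelled 22E EtOH replicate 1, 6 without 22E EtOH replicate 2, 12 without 22E 4OHT replicate 1 and 3 without 22E 4OHT replicate 2. It was 8 without KG1A EtOH replicate 2 and 0 without KG1A EtOH replicate 1, 4OHT replicate 1 or 4OHT replicate 2. With DESeq2 size factors 17 genes were called, 2 higher and 15 lower (11.8% higher against 22.2%). The DESeq2 test called 858, and a normal test of the difference of the per-line changes 1914. As Foxa1 and Foxa2 did not follow the 22E labels, these counts compare labels and no direction of a response is drawn from them.

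KG1A was compared with the in vivo change on FoxA1 and FoxA2 targeting. Of 13511 genes tested in both, 1178 were lower in KNF1F2 than in KN and lower with 4OHT in KG1A, against 402 for independent lists, and 1165 were higher in both, against 383. Another 165 were lower in vivo and higher in KG1A, against 474. Leaving out a KG1A library, which left the spread to the other pair, moved these counts with the number of calls. Across genes, which are not independent replicates, Pearson's r of the log2 changes was 0.615 and Spearman's rho 0.541. Of 2573 genes called in both, 2343 (91.1%) had the same sign. The overlap with both organoid lines was 0 genes, since 22E had 0 calls by edgeR (416 at an unadjusted p under 0.05, and 10 by DESeq2).

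**Figure D3:**
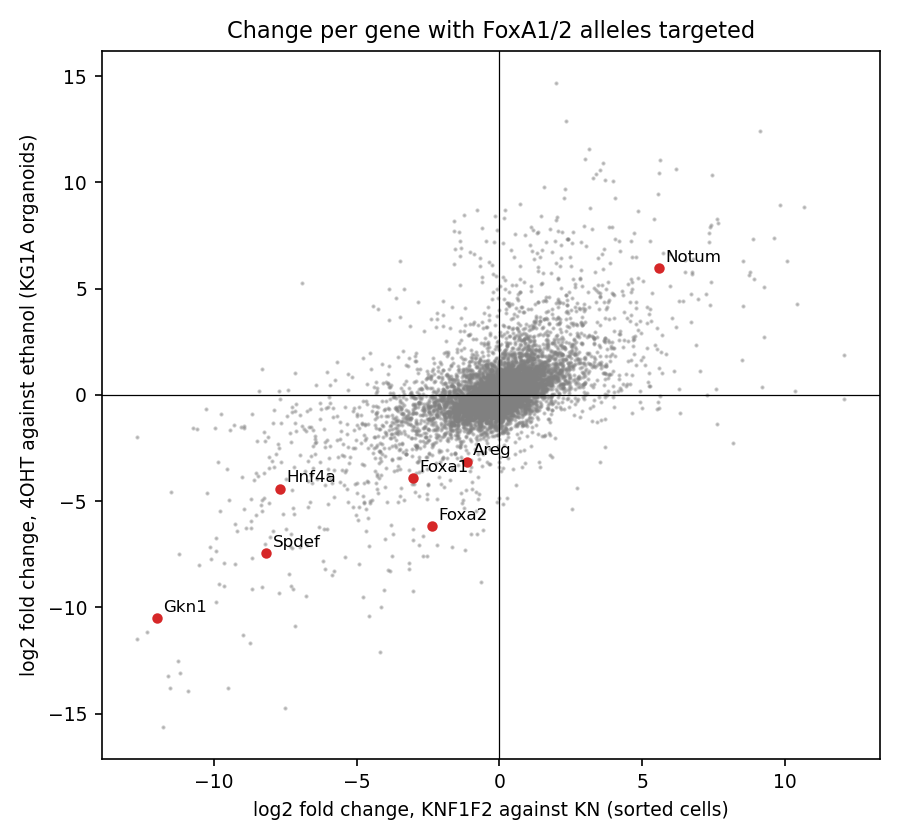
Log2 fold change of each of 13511 genes (points) for KNF1F2 against KN (horizontal axis) and for 4OHT against EtOH in KG1A (vertical axis), with 7 genes labelled. The points rise together (r = 0.615), with Gkn1 at -11.99 and -10.52 and Notum at 5.6 and 5.96 (10.61 in KG1A without EtOH replicate 2).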

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

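The interaction test in this part was planned, and all tests of why the 22E libraries did not follow their labels were chosen after that result was seen. The contrast between libraries labelled 4OHT and EtOH differed between the lines, by the interaction of line and labelled treatment, for 36 genes by edgeR, 858 by DESeq2 and 1914 from the difference of per-line changes. The named ones have a log2 difference, 22E minus KG1A, of 6.90 for Adh7 (an alcohol dehydrogenase), 2.77 for Lpcat2, 2.68 for Syt16, 2.60 for Tmem246, 2.17 for Cth, -10.64 for Mmp7 (a matrix metalloproteinase), -8.27 for Hvcn1, -6.96 for Cldn3 (a claudin), -6.81 for Kif26b and -6.70 for Steap4. In KG1A, mean CPM went with 4OHT from 95.1 to 0.837 for Adh7, from 0.0888 to 101 for Mmp7, from 1.53 to 178 for Cldn3 and from 1.32 to 138 for Kif26b. In 22E, means over the libraries labelled EtOH and over those labelled 4OHT, each pooling 1 library high and 1 low in Foxa1, were 77.2 and 82.1 for Adh7, 1.46 and 1.46 for Mmp7, 136 and 123 for Cldn3, and 3.24 and 2.93 for Kif26b. The calls of Adh7 and Kif26b (edgeR adjusted p = 0.00419) ended without KG1A EtOH replicate 1 (0.119), 4OHT replicate 1 (0.0845) or 4OHT replicate 2 (0.0865). The other 8, with adjusted p of 0.0463 to 0.0496, ended without KG1A EtOH replicate 1 (0.158 to 0.206), EtOH replicate 2 (0.0628 to 0.0923), 4OHT replicate 1 (0.32 to 0.327) or 4OHT replicate 2 (0.285 to 0.339). They also ended without 22E 4OHT replicate 1 (0.0604 to 0.0949), 22E 4OHT replicate 2 (0.0576 to 0.0637) and, except Cldn3, 22E EtOH replicate 2 (0.0746 to 0.124). Mmp7 was at -14.38 without KG1A EtOH replicate 1, -9.12 without KG1A EtOH replicate 2, -9.04 without 22E EtOH replicate 2 and -11.34 without 22E EtOH replicate 1, Hvcn1 at -10.93 and Steap4 at -7.88 without KG1A EtOH replicate 2, and Steap4 at -5.95 and Cldn3 at -6.18 without 22E EtOH replicate 2.

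These differences rest on the 22E labels, which Foxa1 and Foxa2 did not follow, so they show no difference in the response to deletion. Of the 3 ways to split the 22E libraries into pairs, edgeR called 0 genes for the labelled one (416 at an unadjusted p under 0.05), 908 for the split by replicate number (2967 at p under 0.05) and 0 for the other (47 at p under 0.05), so the libraries are structured by replicate number. A difference in depth is argued against, since the lowest total of the libraries low in Foxa1 was 1.10 times that of the libraries high in it. A candidate explanation is that the labels of 22E EtOH replicate 2 and 22E 4OHT replicate 1 were exchanged. The log2 changes of the split this gives had an r of 0.680 with the KG1A response across 13583 genes, against 0.0960 for the labelled split and 0.111 for the other. It cannot be told apart from 1 culture that escaped deletion under 4OHT and 1 that lost the genes without it, since Foxa1 in EtOH replicate 2 was at 12.9% of EtOH replicate 1 under both, and 4OHT replicate 1 at 90.5%.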

How the results depend on the processing

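The log2 Xist covariate, the removal of ribosomal RNA genes, KG1A alone, the omission of 2 libraries together, and the repeats of the overlaps without each library were chosen after seeing the data, and the other alternatives were planned. Over all named genes and alternatives, 4234 repeats stayed on their side of the threshold, 295 lost the call, and 2 gained one. For list tests these were 1420, 42 and 58. The direction turned in 23 repeats of genes and 76 of lists (6 of them by fry), all of them called in neither fit. For the counts of called genes, DESeq2 size factors, library totals, both count filters and DESeq2 stayed within 1.5 times in the in vivo comparisons and in KG1A. Leaving out single libraries gave 5876 to 6666 genes for KN against K, 5242 to 5517 for KNF1F2 against KN and 3473 to 5236 for KN against N. Without K replicate 1 and KN replicate 2 together 5887 genes were called for KN against K, and without KN replicate 2 and KNF1F2 replicate 3 together 4379 for KNF1F2 against KN. At the spread between the libraries labelled alike in 22E, 0% of simulated 2-fold and 4-fold changes were recovered, so changes of that size were not detectable there.

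With at least a 2-fold change, counts were 4226 for KN against K, 3768 for KNF1F2 against KN, 2253 for KN against N and 2276 for KG1A, and the overlaps were 1088 (higher in KN than in K, lower in KNF1F2) and 413 (higher in KN than in both K and N), since that setting only removes genes. KG1A alone gave 1178 for the overlap with KNF1F2, where both lines gave 0. KG1A counts ranged from 1784 to 9159 over the libraries left out. For 22E, DESeq2 called 10 genes. For the interaction of line and treatment, counts were 17 with DESeq2 size factors, 17 with at least 10 counts in every library of a group, 858 by DESeq2, 1914 from the difference of per-line changes, and 0 to 242 over the libraries left out. Called lists with an estimated correlation numbered 1 of 8 for KN against K, 1 of 7 for KNF1F2 against KN, 0 of 9 for KN against N, 0 of 1 for 22E and 0 of 6 for KG1A. Fry called 0 lists in 22E and 15 in KG1A. The filter on 10 counts called 2 lists in 22E, and leaving out single libraries 0 to 3. For these changes the cause was not tested.

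Replicate numbers are shared between groups but do not pair the samples by any label, and correlations of same-number deviations ran from -0.094 to 0.161 in vivo, were 0.760 in 22E and 0.052 in KG1A. With the replicate block, 7067 genes were called for KN against K, 6286 for KNF1F2 against KN, 4743 for KN against N, 0 for 22E (1383 at an unadjusted p under 0.05) and 4438 for KG1A. The block gave 1912 genes for the interaction and 3 called lists in 22E, and the cause was not tested.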

Other observations

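The fits with the request as a term and the 6-library fits of the groups were planned, and the other tests in this part were chosen after the results were seen. So were the genes of the first 2 paragraphs, except that the rule for named genes took Meg3, Rian and Dlk1 for KN against N, Chil4 for KG1A, and Xist for KN against K and KN against N. Maternally expressed transcripts of the imprinted Dlk1-Dio3 region differed between genotypes. Meg3 was at 588 ± 132 CPM in K, 57.0 ± 11.1 in KN and 0.689 ± 0.855 in KNF1F2, with no count in N. Rian was at 494 ± 213, 36.4 ± 7.65 and 0.623 ± 0.511 CPM in the same order, with no count in N, and the paternally expressed Dlk1 at 299 ± 233, 10.2 ± 1.29 and 0.115 ± 0.200. From K to KN, Meg3 fell by 3.37 (SE 0.36, edgeR adjusted p = 2.83e-05). In K replicate 1, the only K library of KN's request, Meg3, Rian and Dlk1 were at 445, 250 and 30.0 CPM, and with the request as a term the log2 change of Dlk1 from K to KN was -1.55 in place of -4.87. From KN to KNF1F2 Meg3 fell by 6.33 (SE 0.50, edgeR adjusted p = 3.13e-06; -8.08 without KNF1F2 replicate 2). In KN Meg3 was at least 1646-fold, Rian at least 1053-fold and Dlk1 at least 295-fold higher than in N.

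The chitinase-like gene Chil4, uncertain against its paralogs, was at 15608, 2549.7 and 16265 CPM in the KNF1F2 libraries, 558.5, 82.7 and 91.0 in KN, 3.56, 22.9 and 4.29 in K, and 11143, 465 and 452 in N. KNF1F2 was higher than KN (log2 change 5.55, edgeR adjusted p = 0.00984; 7.05 without KN replicate 1). In KG1A, 4OHT raised Chil4 to 126 ± 6.47 CPM (log2 change 9.46, 14.60 without EtOH replicate 2). Xist was at 1740 to 2978.5 CPM in K replicates 2 and 3, KNF1F2 replicate 1 and N replicates 1 and 3, and at 1.53 or less in the 7 other libraries, among them all of KN. In those 7 the Y-linked Ddx3y was at 36.3 to 62.3 CPM.

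Of the endothelial genes, 9 of 12 were lower in KN than in K. A lower share of the sorted main cell type in K stays open, since other cell types need not vary together. The upper quartile of endothelial changes (-1.45) lay 2.63 below the lower quartile of macrophage and neutrophil changes (1.19). Of those 14 genes 2 rose and 1 fell. Fibroblast and smooth muscle markers went down with the endothelial ones, with a median log2 change of -0.97 (camera adjusted p = 0.112, and 0.535 with an estimated correlation). For Esam, endothelial cells carried through the sort are argued against, because the lowest ratio of Esam to Pecam1 in K (2.7) was 3.59 times the highest in N (0.752) and lay above those in KN (0.69 to 1.24; 3.82 to 7.06 in KNF1F2). For the other 11 markers, of which 8 fell and 0 rose with a median log2 change of -1.76, carried-over endothelial cells, which a gate on GFP would remove, cannot be told apart from a change in the tumour cells, since both predict a joint fall. Pecam1 itself was at 28.8 ± 5.52 CPM in K and 10.1 ± 5.04 in KN.

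The 7069 genes called between KN and K were weighed against the library requests and the sex difference (Xist). With log2 Xist CPM as a covariate 5980 were called in the same direction and 0 turned, which argues against that difference as the whole cause. With the request as a term 6074 were called in the same direction and 0 turned. That term leaves K replicate 1 alone to stand for K, so the request stays open as a cause. In 6-library fits edgeR called 6776 genes for KN against K, 7780 for KNF1F2 against KN and 4415 for KN against N, and the highest count among the other splits was 0 in each. Only 1 of 10 splits, the real one, was as large in each of the 3, and with 10 splits the share cannot fall under 0.1, so no statement about chance follows.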
